A study of Cucumis sativus with 4 samples.

How the data were processed

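RNA-seq was carried out on axillary (lateral) buds of cucumber, Cucumis sativus, taken from the same node of plants that were 2 months old. The labels give 2 libraries from wild-type plants and 2 from CsBRC1-RNAi plants, which carry an RNA interference construct made from a 585-bp piece of the CsBRC1 coding sequence. An empty-vector control is also described in the labels' protocols, but the genotype label of both control libraries is wild type, and they are called so here. Nothing in the labels says whether the 2 libraries of a group came from separate plants, pools or transgenic lines, so the p-values measure only the spread between these libraries, which may be technical.

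Reads were aligned and counted with HISAT and HTSeq, per the submitters' processing notes. Their versions, the genome build, the annotation release and any use of strand are not given in the sources used here. The deposited table holds 1 normalised signal value per gene and library, called CPM in its name. It lists 17770 gene identifiers of the form Csa, a chromosome digit or UN, G and a running number. UN stood in place of a digit in 78 of the genes tested, called unplaced here. The columns sum to between 905783 and 1134691, so they are not plain CPM. In all 4 columns 100% of the values were whole multiples of the column's smallest value above 0 (within 1e-06 of a whole number), and dividing by it gave whole reads. The effective library sizes implied by the values (35753863, 28222226, 25484957 and 30433207 reads for wild type 1, wild type 2, CsBRC1-RNAi 1 and CsBRC1-RNAi 2) equalled to the read those that edgeR's trimmed mean of M-values (TMM) gave on the recovered reads. The deposited signal values therefore have the form of TMM-scaled CPM. Every gene in the table had at least 1 CPM, taken over the table's total of recovered reads, in at least 2 libraries, so genes silent in all libraries are outside the table. No row lacked a gene identifier, and 0 columns came from outside the series.

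The recovered reads summed to 32385236 and 26912976 in wild type and 28917558 and 31050990 in CsBRC1-RNAi. A single read was worth 0.028, 0.0354, 0.0392 and 0.0329 in the same order, and a count of 0 allows up to 3 reads, a value of 0.0839, 0.106, 0.118 and 0.0986. Intervals and floors cover counting error only. The replicate libraries of each group were distinct: the chi-square statistic of their reads per degree of freedom was 135 in wild type and 89.6 in CsBRC1-RNAi, where sampling noise alone gives about 1.

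The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with a trended prior variance, no block, and genes with a value of at least 1 in at least 2 libraries (17726 genes, 44 removed). Fold changes on this scale understate the change of low genes. P-values were adjusted by Benjamini and Hochberg's method over all genes tested, with a threshold of 0.05. Simulated libraries were drawn from the means, dispersions and sizes of these 4 libraries, with 200 of 17726 genes changed. The changed genes were taken only from genes with a mean value of at least 5, so the result does not cover lower genes. The test called 76% of the genes changed 4-fold and 4% of those changed 2-fold, with 12 unchanged genes called. In this single simulated set those 12 were a larger share of the calls than the 0.05 threshold allows on average. With no gene changed it called 2 genes. The neighbour test was also checked on simulated calls and gave a permutation p of 0.204 for calls at random and 0.000999 with 40 planted pairs. As the identifiers carry no names, the genes named were the 2 largest rises and the 2 largest falls among genes past the threshold with a mean of at least 5 in the higher group and no overlap between groups.

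Alternatives fixed before the data were examined were pseudocounts of 0.5 and 2, no filter, a mean value of at least 5, median-of-ratios scaling, quantile normalization, the replicate number as a block, a constant prior variance, leaving out each library, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads, a fold of at least 2, and an adjusted p under 0.1. The edgeR and DESeq2 fits were run on the recovered reads. The correlation across genes of the replicate 1 minus replicate 2 differences in both groups was 0.038, and no label says that the numbers mark a shared batch, so the libraries were not treated as pairs.

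None of the table's identifiers matched the gene identifiers, locus tags, symbols, synonyms or accessions of the RefSeq cucumber gene table of 23999 genes (0 of 17770). No names, functions, lengths or coordinates were therefore assigned. The levels of CsBRC1, CsPIN1b and CsPIN3, and the lists of hormone, cell cycle, cell type and stress genes fixed before the data were examined, were not analysed here. The digit in an identifier was read as the chromosome and the running number as the order along it, by the naming convention of these identifiers, without a check against an assembly. The sets of genes absent from 1 genotype and the neighbour test were defined after the values had been seen.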

Results

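CsBRC1 is the cucumber member of the BRANCHED1 group of TCP transcription factors, which hold back the outgrowth of axillary buds in flowering plants. The series compares the transcriptome of axillary buds in which CsBRC1 was targeted by RNA interference with that of wild-type buds, and its title places the auxin efflux carriers CsPIN1b and CsPIN3 downstream of CsBRC1. Each genotype had 2 libraries, with between 26912976 and 32385236 recovered reads per library. The targeted gene and both carriers were not analysed here, because the table lists gene identifiers without names, so the grouping rests on the labels and was not checked by the level of CsBRC1.

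The libraries separated by genotype. Across 17726 genes, the CsBRC1-RNAi libraries were the most alike, with a Pearson correlation of log2 values of 0.97 and 674 genes (3.8%) that differed at least 2-fold between them. The wild-type libraries had a correlation of 0.953 and 1305 such genes (7.4%). Between genotypes the correlations ran from 0.869 to 0.917. Wild type replicate 1 stood nearer to the CsBRC1-RNAi libraries, with 2705 and 2245 genes at least 2-fold apart, than wild type replicate 2 did, with 4497 and 4239. The first principal component, which held 72.6% of the variance, placed the CsBRC1-RNAi libraries at 54.6 and 52.2, wild type replicate 1 at -35.3 and wild type replicate 2 at -71.4. On the second component, with 15.2% of the variance, wild type replicate 1 stood apart at 40.2, against -28.5 for wild type replicate 2 and -1.7 and -10 for CsBRC1-RNAi replicates 1 and 2. Genes are not independent replicates, so these correlations describe the libraries and carry no p-value.

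More of the called genes rose than fell in the CsBRC1-RNAi buds, while over all genes tested the median log2 fold change was -0.006. Of 17726 genes tested, 640 (3.61%) differed between the genotypes by limma at an adjusted p under 0.05, of which 390 were higher and 250 were lower in CsBRC1-RNAi. Among the genes called, those that rose had a median log2 fold change of 1.94 (quartiles 1.55 and 2.44). Those that fell dropped by a median of 1.77 on the log2 scale (quartiles 1.45 and 2.28). The test mostly calls large changes: in the simulated libraries it called 76% of 4-fold and 4% of 2-fold changes. These medians therefore describe the called genes and not the size of change over all genes. In that simulation 12 unchanged genes were also called, a larger share of its calls than the 0.05 threshold allows on average. The 640 calls may likewise hold more false calls than that. A rise of at least 8-fold was fitted for 45 of the called genes and a fall of that size for 12. In all 640 genes the values of the 2 genotypes did not overlap. The same held for 67.1% of all genes tested, where chance ordering of 2 against 2 libraries gives 33.3% on average over the 3 splits. Genes vary together, so a single split can exceed that average without an effect of genotype. At an unadjusted p under 0.05 the count was 5761 genes, with 3143 higher and 2618 lower. The count of calls moved with every library left out: without wild type replicate 2, limma called 0 genes (4571 at an unadjusted p under 0.05), edgeR 0 and DESeq2 1896, and without wild type replicate 1 limma called 3531. Without CsBRC1-RNAi replicate 1 limma called 63 genes and without CsBRC1-RNAi replicate 2 it called 3.

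**Figure D1:**
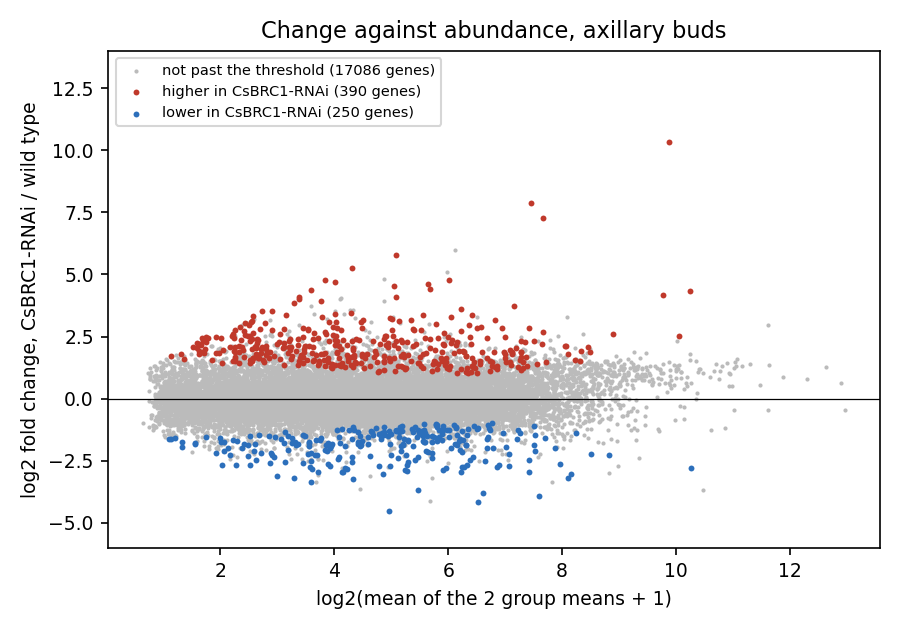
Each point is a gene, with log2 of the mean normalised value plus 1 on the x axis and the log2 fold change of CsBRC1-RNAi over wild type on the y axis. The 390 genes past the threshold that were higher are red, the 250 that were lower are blue, and the others are grey; the largest rises reach further from 0 than the largest falls.

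The largest rise was that of Csa3G104850, which was nearly silent in wild type. It had 1 and 0 reads in the wild-type libraries and normalised values of 530 and 3230 in CsBRC1-RNAi replicates 1 and 2, a mean of 1880 ± 1910 (SD, n = 2). Its log2 fold change was 10.34 ± 0.81 (SE) with an adjusted p of 0.018 by limma. The size of this fold depended on the pseudocount and on single libraries: it was 11.32 and 9.35 with pseudocounts of 0.5 and 2, 11.64 and 9.03 without CsBRC1-RNAi replicates 1 and 2, and 16.54 by edgeR. With 1 wild-type read in all, the ratio of reads was 128000 with an exact 95% Poisson interval from 23000 to 5060000, which covers counting error only. Csa4G637770 had 2 reads in each wild-type library and values of 105 and 592 in CsBRC1-RNAi, with a log2 fold change of 7.88 ± 0.78 and an adjusted p of 0.0216 by limma. Its fold was 8.8 and 6.94 with pseudocounts of 0.5 and 2, 9.12 and 6.64 without CsBRC1-RNAi replicates 1 and 2, and 12.35 by edgeR. Both genes were several times higher in CsBRC1-RNAi replicate 2 than in replicate 1, so that on the linear scale the SD was about as large as the mean. Without wild type replicate 2 their adjusted p-values by limma were 0.0889 and 0.0936.

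The largest fall was that of Csa4G625060, from 71.8 and 45.4 in wild type (58.6 ± 18.6, SD, n = 2) to 2.28 and 0.986 in CsBRC1-RNAi (1.63 ± 0.912), 35.9-fold lower. Its log2 fold change was -4.51 ± 0.36 (SE), with an adjusted p of 0.018 by limma, and of 0.0867 without wild type replicate 2 and 0.0861 without CsBRC1-RNAi replicate 2. Csa6G501990 went from 68.8 and 282 in wild type to 4.59 and 10.1 in CsBRC1-RNAi, with a log2 fold change of -4.16 ± 0.7 and an adjusted p of 0.0472 by limma. The log2 fold change was -5.17 without wild type replicate 1, -3.15 without wild type replicate 2 and -3.67 without CsBRC1-RNAi replicate 1. This limma call was at the edge of the threshold. The adjusted p was 0.0521 among genes with a mean of at least 5, 0.0542 with a constant prior variance and 0.0573 by edgeR. It was lower by DESeq2 (4.2e-11) and by limma with the replicate block (0.0059), settings that called more genes. It was 0.171 by limma without CsBRC1-RNAi replicate 1, 0.0998 without CsBRC1-RNAi replicate 2 and 0.0966 without wild type replicate 2.

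**Figure D2:**
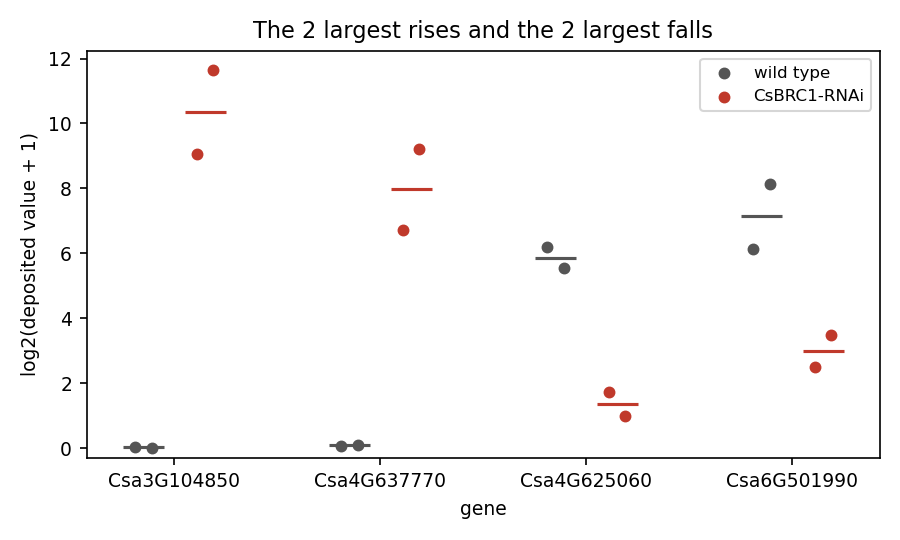
Points are single libraries (2 per genotype) and short lines their means, on a scale of log2(normalised value + 1), for the 2 genes with the largest rise and the 2 with the largest fall. Csa3G104850 and Csa4G637770 lie at 0 or close to it in wild type, while both falling genes keep values above 0 in CsBRC1-RNAi.

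Changed genes were found at every level of abundance. Among the 4992 genes with a mean value under 10, 123 were higher and 51 lower in CsBRC1-RNAi; among the 10469 genes between 10 and 100, 209 were higher and 166 lower; and among the 2265 genes of 100 or more, 58 were higher and 33 lower. The share of genes called was 3.49% in the lowest and 4.02% in the highest class. This difference did not pass a two-sided Fisher's exact test across genes (p = 0.28), which treats genes as independent. The most abundant class had a median log2 change of 0.2 over all its genes, called or not, against -0.02 and -0.03 in the other classes. This median was 0.2 with median-of-ratios scaling, 0.05 after quantile normalization (-0.04 over all genes), and 0.17 to 0.23 when any of the 4 libraries was left out. The 100 most abundant genes of each library took 12.45% and 14.26% of its reads in wild type and 20.25% and 15.77% in CsBRC1-RNAi replicates 1 and 2.

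A small set of genes was all but absent in wild type. In 30 genes the wild-type libraries held 3 or fewer reads together, while both CsBRC1-RNAi libraries reached a value of at least 1; the opposite held for 8 genes. The 30 genes had a median value of 9 in CsBRC1-RNAi, 13 of them had a mean of at least 10, and the highest mean was 1880; the highest wild-type mean among the 8 genes was 3.63. These genes are not independent replicates, so no p-value is given for the split of 30 against 8. By limma, 10 of the 30 and 2 of the 8 were past the threshold. Both sets were picked by the same contrast, so calls among them, by limma or DESeq2, are not separate evidence. Of the 30, limma called 0 without wild type replicate 2, 18 without CsBRC1-RNAi replicate 1 and 1 without CsBRC1-RNAi replicate 2, and DESeq2 on all libraries called 30. With a value under 0.5 in both libraries as the limit for absence, the sets held 113 and 58 genes.

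The share of genes called was similar on each chromosome. By the chromosome digit in the identifiers, the share called ran from 3.23% (56 of 1736 genes on chromosome 7) to 4.01% (118 of 2945 on chromosome 6). No chromosome differed from the rest by a two-sided Fisher's exact test (adjusted p = 1 for each of 8 groups, the unplaced genes included). That test treats genes as independent, which they are not, so it cannot show that the chromosomes are alike. On each of the 7 chromosomes more of the called genes were higher than lower in CsBRC1-RNAi. The counts ran from 31 against 25 on chromosome 7 to 55 against 25 on chromosome 2.

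**Figure D3:**
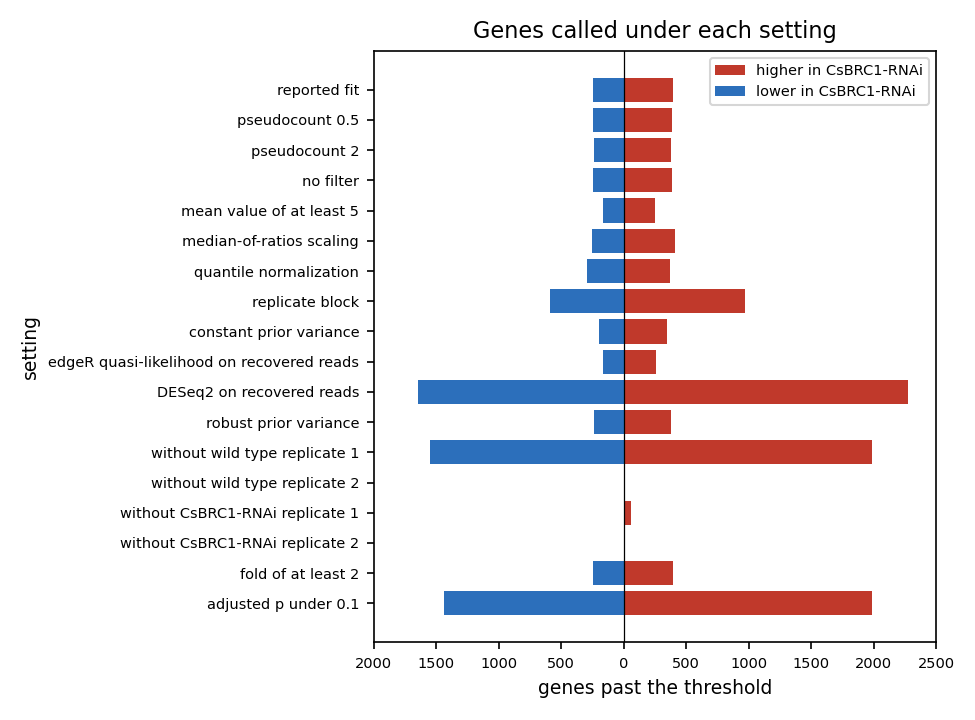
Bars give the number of genes past the threshold that were higher (red, to the right) or lower (blue, to the left) in CsBRC1-RNAi, for the reported fit (640 genes) and each alternative setting, apart from the edgeR and DESeq2 fits that also left out a library. Among the settings drawn, the count ran from 0 genes without wild type replicate 2 to 3917 with DESeq2 on recovered reads.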

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

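Of the results, the fits with both a left-out library and edgeR or DESeq2, the robust prior, both definitions of absence and the neighbour counts were chosen after seeing the data. The 640 calls (390 higher, 250 lower) became 416 (250 and 166) among genes with a mean of at least 5 and 422 (255 and 167) with edgeR. They became 3917 (2270 and 1647) with DESeq2 and 3426 (1989 and 1437) at an adjusted p under 0.1, a looser threshold. With a mean of at least 5, 551 of the 640 genes were still tested and 416 were called. Removal of genes from the test therefore does not account for all of the lost calls. The cause of these shifts was otherwise not tested. Of the 640 genes, 410 were also called with edgeR and all 640 with DESeq2, which gave no missing adjusted p. With the replicate block the count was 1561 (972 and 589); the numbers are not shown to pair the libraries. The other settings (both pseudocounts, no filter, both scalings, constant or robust prior, a fold of at least 2) gave 542 to 668 calls, and the share that was higher went from 60.9% to 55.5% at the lowest, after quantile normalization. Leaving out a library gave 0 to 3531 calls with limma (0 to 1982 higher, 0 to 1549 lower), which in the order wild type 1, wild type 2, CsBRC1-RNAi 1 and CsBRC1-RNAi 2 left out were 3531, 0, 63 and 3. In the same order edgeR gave 3402 (1852 higher, 1550 lower), 0, 99 (97 and 2) and 24 (22 and 2), and DESeq2 gave 4383 (2613 and 1770), 1896 (1281 and 615), 911 (565 and 346) and 1272 (754 and 518). Such a fit leaves 1 genotype with a lone library, assumed to vary like the other genotype. The sets of genes absent from one genotype grew from 30 to 113 and from 8 to 58 with a value under 0.5 as the limit. The gene list tests, and the test of CsBRC1 and the PIN genes, were not run. Depth limits little here, since 1 read was worth at most 0.0392. In simulated data of 2 against 2 libraries the changed genes all had a mean of at least 5. Of these, limma called 76% of those changed 4-fold and 4% of those changed 2-fold. Most changes of the smaller size were therefore missed there. The simulation changed 200 genes, fewer than the 640 called here, which makes its cutoff in p stricter. The shares called in the real data may therefore be higher. In the simulation 12 unchanged genes were also called, a larger share of its calls than the threshold allows on average.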

Other observations

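The tests of wild-type depth, of mixing, of scaling and of the other splits were chosen only after the results they bear on were seen, as were the neighbour counts under other settings. The sets of absent genes were also defined after the values had been seen. Genes that changed in the CsBRC1-RNAi buds lay next to each other in the gene numbering more often than in shuffled calls. In 52 pairs of neighbouring tested genes both members were called in the same direction, against a mean of 12 pairs (middle 95% from 6 to 19) when the calls were shuffled within chromosomes 10000 times, a permutation p of 1e-04, the smallest these shuffles can give. In 9 neighbouring pairs the members were called in opposite directions, a count that was not set against shuffles. The 52 pairs formed 42 runs holding 94 genes, 14.7% of the changed genes placed on a chromosome, and the longest run had 4 genes, which were lower in CsBRC1-RNAi. Counting only identifiers whose numbers lie at most 10 apart, 39 pairs were found against 8.3 in shuffles. The excess was also present in the calls of edgeR (39 pairs against 5), of DESeq2 (651 against 442.8), of limma without wild type replicate 1 (518 against 356.6) and of limma without CsBRC1-RNAi replicate 1 (3 against 0.2). Without wild type replicate 2 or CsBRC1-RNAi replicate 2 there were 0 and 3 calls and no pair. Placement by chance (52 pairs) and uneven numbers of changed genes between chromosomes (permutation p = 1e-04 after shuffling within them) are both argued against. Tandem copies with shared regulation, reads shared between near-identical copies, overlapping genes and gene models split in the annotation may each give such pairs, and stay open, since neither sequences nor names were used here.

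For the 30 genes nearly absent from wild type and present in both CsBRC1-RNAi libraries, too few wild-type reads are argued against, since the wild-type libraries together held 98.9% as many recovered reads as the CsBRC1-RNAi libraries. A single block of a chromosome that differs between the plants compared is argued against as the whole source. The 30 genes lay on 7 chromosomes, with 23.3% (7 genes) on the commonest, chromosome 6 (exact 95% interval 9.9% to 42.3%). They did hold 4 neighbouring pairs, against 0.05 in shuffles (permutation p = 1e-04). The interval treats the genes as independent, so with such pairs it is likely too narrow. Several small regions that differ between the plants, or clusters of related genes switched on together, may account for part of the set. A response to the silencing, a difference in bud stage and a difference in plant background cannot be separated with 1 comparison and no names, and were not tested.

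Wild type replicate 1 lay between wild type replicate 2 and the CsBRC1-RNAi libraries on the first principal component, and apart from all 3 on the second. Over all genes tested, 2705 and 2245 genes were at least 2-fold from the CsBRC1-RNAi libraries for wild type replicate 1, and 4497 and 4239 for wild type replicate 2. Among 672 genes at least 4-fold apart between wild type replicate 2 and CsBRC1-RNAi, wild type replicate 1 stood a median of 27.5% of the way on the linear scale. These genes were picked by the distance of wild type replicate 2, which by itself places replicate 1 part of the way, so this share does not measure a shift. CsBRC1-RNAi RNA mixed into wild type replicate 1 is argued against by 6 genes absent from wild type replicate 2 and at 10 or more in both CsBRC1-RNAi libraries. Over these 6 genes the upper quartile of the same share was 0.00111%. Over the 672 genes the median share was 17.4% in genes higher and 74.7% in genes lower in CsBRC1-RNAi, but the choice of genes bears on both. The median share on the log2 scale was 40% as deposited and 39.1% after quantile normalization, so it changed little with the scaling. This cannot decide whether scaling played a part, because the choice of genes places wild type replicate 1 part of the way under either scaling. A difference in the growth stage or the makeup of the sampled buds may underlie the distance between the wild-type libraries. With 2 wild-type libraries it cannot be told which of them, replicate 1 or replicate 2, is the unusual library. That explanation stays open, as the labels give no such detail and no biological explanation was tested.

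The 4 libraries can be split into 2 and 2 in 3 ways. The real split called 640 genes and the highest other split called 0, so 1 of the 3 splits called as many. With 3 splits the share cannot fall under 0.05. Each other split puts 1 library of each genotype in both groups, so any genotype difference widens the spread within groups. Such splits could hardly call genes, and no conclusion is drawn from their 0 calls.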
